A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

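Both channels of 4 2-colour arrays held the same RNA of untreated yeast cells, per the labels. The values were the deposited table of 1 log2 ratio per feature and array. How the authors made them, including the scanner, the software, the background correction, the feature filter, any normalization and the dye in the numerator, is not given in the sources used here. Intensities of the separate channels were not used here, so signal over background and saturation are unknown. That the deposited ratios are on the log2 scale was read from the values: 373 of 3297, or 11.3%, equalled log2 of a ratio of whole numbers up to 10 within 0.00005. Read as natural logarithms 1.46% did so, read as log10 3.31%, and after a shift of all values 0.149%. Such ratios would not survive a rescaling or centring, so none was seen in the deposited values. A feature with such a ratio, or with a missing value, on any array is called dim here. That its signal was low is an assumption, which was not measured, since intensities were not used. The counts of silent and abundant genes with a dim feature, given under Results, bear on it. This definition was made after the values were seen.

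Gene names came from the platform annotation, matched by Entrez identifier to the R64 gene table. All 724 features with 1 gene matched and 0 symbols changed, and they named 353 genes, 350 of them with 2 features. A further 10 features had several genes and 162 had no gene name in that annotation, and these entered no gene test. No coordinates are printed, since no genome build was named. The 4 arrays formed 1 group, with numbers taken from the labels. By a rule fixed before the data were examined, the values were to be used as deposited if every array median lay within 0.1 of 0, and otherwise every array was to be centred. The medians were -0.058, -0.25, -0.19 and -0.24, 3 of them beyond that limit, so all 4 arrays were centred on their medians. Features of a gene were averaged per array on the log2 scale, and genes with values on at least 3 arrays were tested, which left out 8. Missing values per array numbered 66, 87, 78 and 56.

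Each gene was tested against 0 with limma's lmFit on an intercept and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The prior had 1.38 degrees of freedom beside 3 of the residuals. The 21 gene lists were written before the data were examined. Lists of at least 3 measured genes, 18 in all, were tested with camera, with a preset correlation of 0.01 and with an estimated one, and with fry, over genes with values on all arrays. The spread of silent and abundant genes was compared by permuting genes 100000 times, and intervals of the intraclass correlation came from 2000 bootstraps of genes.

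Named genes followed a rule fixed beforehand: the 10 higher and 10 lower genes of smallest p with the same sign on every array, the 5 of largest SD, a set of wall and control genes chosen beforehand, and in each list the member of largest absolute mean and of largest SD. Outside this rule, GAS4, GAS5, UTR2, SCW10, GNA1, PCM1, PSA1, CCW12, TIR3, FIG2, PKC1, BCK1, HSP12, FBA1, ENO1, KRE1, CWH41, TDH2, TDH3, KTR6, KTR2, WSC4, BEM2, PTP3, YPD1, STE11, STE20, STE50, PRM5, FLO10, GPI1, SMK1, SUN4 and PGK1 are named to complete the counts of their lists or as examples, after their values were seen. The ACT1 features and the variance components were also examined after the values were seen.

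The steps were tested on simulated data with 345 genes and the observed spread, over 20 runs. For the test of single genes, 7.00%, 45.5% and 68.8% of genes with a true mean of size 0.25, 0.5 and 1 were called, and 0.386% of unchanged genes. With 3 arrays these shares were 0.250%, 5.25%, 43.8% and 0.211%. A list of 15 genes shifted by 0.5 was called in 100% of runs and unchanged lists in 2.5% at an unadjusted p of 0.05. The simulated genes were drawn independently, so these shares do not cover lists of correlated genes. The estimated correlation was 0.247 in the abundant and 0.633 in the housekeeping list. For the intraclass correlation, run on 300 genes, 0.645 was recovered for 0.64 simulated. Alternatives covered centring, the number of arrays needed, features kept apart, scaling, quantile normalization, each array left out, robust and weighted fits, and other thresholds. Leaving out genes with dim features, centring by blocks of 112 rows, averaging by the median, leaving out glycolytic genes (the housekeeping list without ACT1) and the variance components without each array were added after the data were seen. R 4.3.3 with limma 3.58.1 was used for statistics, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 for figures.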

Results

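The series held 4 arrays of one kind, called yellow experiments in the labels. In each of them the same total RNA was labelled with both Cy3 and Cy5 and hybridised to a 2-colour array devoted to yeast cell wall genes. The RNA came from untreated cells of Saccharomyces cerevisiae BY4741, a haploid laboratory strain of mating type a. The cells were cultured in rich medium at 24 °C, brought back from an overnight optical density of 0.8 to 1 down to 0.2, and harvested 6 h later. The table listed 896 features, and arrays 1 to 4 held values for 830, 809, 818 and 840 of them. A single gene was named for 724 features, and 345 genes with values on at least 3 arrays were tested, 327 of them with values on all 4. The number of arrays limits the precision. Nothing in the labels says that the arrays came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

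The first comparison asked which genes gave a ratio other than 1 although both channels held the same RNA. CCW14, which encodes a glycoprotein of the inner cell wall layer, lay above the array median on every array, with a mean log2 ratio of 1.03 ± 0.195 (SD, n = 4), a 2.05-fold departure. CWP2, a major wall mannoprotein, and AGA2, the adhesion subunit of a-agglutinin, were also higher, at 0.77 ± 0.265 and 0.71 ± 0.123 (SD, n = 4). On the other side lay DDR48, a stress-induced gene, at -0.77 ± 0.0453, MNN9, a subunit of Golgi mannosyltransferase complexes, at -0.76 ± 0.108, and RPC34, a subunit of RNA polymerase III, at -0.68 ± 0.0193 (SD, n = 4). Higher and lower are given relative to the array median and in the direction of the deposited ratio, whose numerator dye is not given in the sources used here.

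Among the genes of smallest p, the higher group further held CYC8, a transcriptional corepressor, at 1.19 ± 0.252, ECM30 at 1.29 ± 0.359, TPI1, the glycolytic triose phosphate isomerase, at 0.62 ± 0.184, TIR1, a cold-inducible wall mannoprotein, at 0.56 ± 0.157, MKK2, a kinase kinase of the cell wall integrity pathway, at 0.70 ± 0.229, and HOG1, the osmotic stress MAP kinase, at 0.55 ± 0.148. SPR1, a sporulation-specific exo-1,3-beta-glucanase, was measured on 3 arrays, at 1.42 ± 0.317. The lower group further held QRI1, a UDP-N-acetylglucosamine pyrophosphorylase, at -1.49 ± 0.467, YAP1801, a clathrin assembly protein, at -0.90 ± 0.234, ARO10, a decarboxylase of amino acid breakdown, at -0.71 ± 0.158, ECL1 at -0.66 ± 0.0385, ROT1, a chaperone of the endoplasmic reticulum, at -0.64 ± 0.102, GCV2, a subunit of glycine decarboxylase, at -0.55 ± 0.121, and RBK1, a ribokinase, at -0.50 ± 0.0457. Of these 20 genes, CYC8, ECM30, SPR1, YAP1801 and QRI1 had a dim feature, that is, one with a missing value or a ratio of small whole numbers on some array. The SD between arrays leaves out differences between duplicate features. These averaged 1.14 for ECM30, 0.909 for QRI1, 0.811 for SPR1, 0.63 for CYC8 and 0.353 for MKK2. For the others of the 20 they were 0.197 or less, and the median over genes without a dim feature was 0.081. The plot of the 20 genes shows the value on each array. Their adjusted p-values from limma ran from 0.0207 for CCW14, CYC8, DDR48, RPC34, ECL1 and MNN9 to 0.0347 for CWP2, SPR1, HOG1, TPI1, TIR1 and MKK2.

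**Figure D1:**
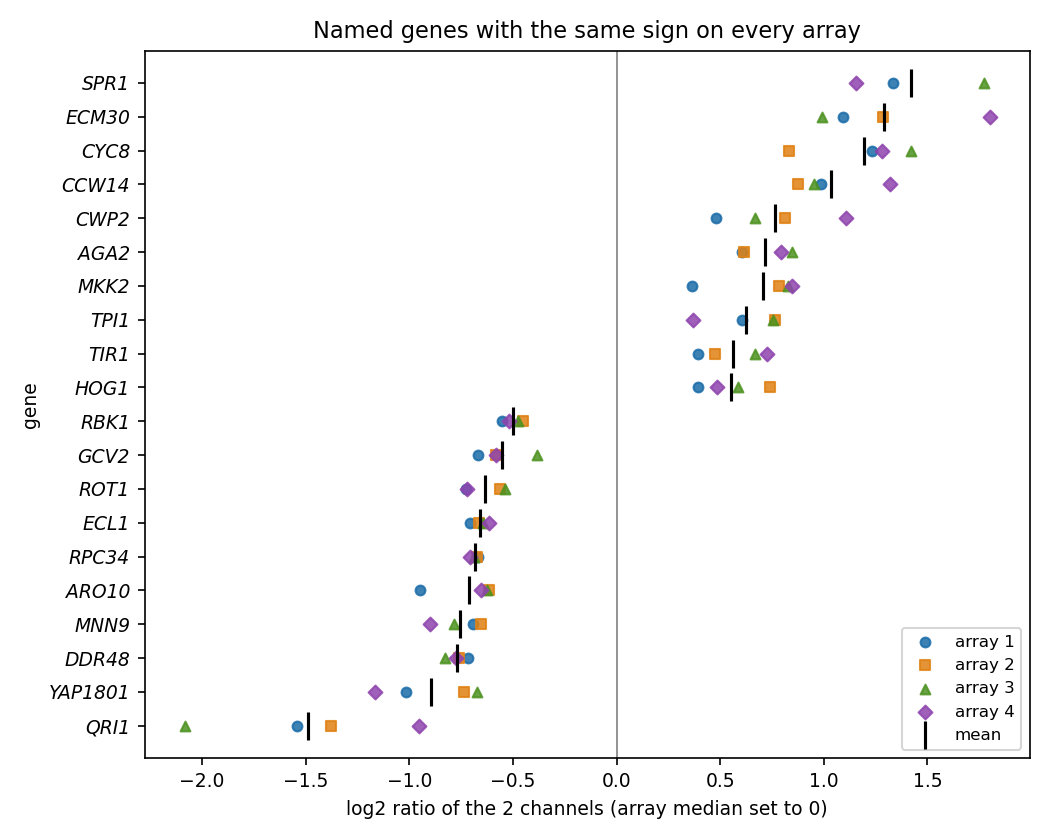
Log2 ratio of the 2 channels, with each array median set to 0 (horizontal axis), of the 10 higher and 10 lower genes of smallest p that had the same sign on every array with a value (vertical axis). Symbols stand for arrays 1 to 4 and black bars for the mean; SPR1 had no value on array 2, and MKK2 and ARO10 lay apart from the rest on array 1.

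In the limma fit, 86 of 345 genes passed an adjusted p of 0.05, 37 of them higher and 49 lower, and 143 genes passed an unadjusted p of 0.05. Of the 86, 13 lay beyond 2-fold and 44 under 1.5-fold, with a median departure of 1.48-fold. The ratio had the same sign on every array with a value for 177 genes, or 51.3%, against 12.5% by chance with 4 arrays. With 3 arrays the calls ended: 0, 0, 1 and 0 genes passed without arrays 1, 2, 3 and 4, with 115, 119, 114 and 118 at an unadjusted p of 0.05. The smallest adjusted p-values in these limma fits were 0.0653, 0.0858, 0.0461 and 0.0697. Used as deposited, with array medians of -0.058, -0.25, -0.19 and -0.24, the values gave 112 calls, 21 higher and 91 lower.

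The second comparison asked whether functionally related genes departed from 1 together. Over all 345 genes 24.9% were called, and the counts in each list are to be read beside that share. Among abundant transcripts, 4 of 14 measured genes were higher and 0 lower, with a list median of 0.48, and 0.29 as deposited. The 4 were the glycolytic genes CDC19 and FBA1, at 0.73 ± 0.350 and 0.72 ± 0.337, and the wall protein genes CWP2 and CCW12, the last at 0.53 ± 0.183 (SD, n = 4). Adjusted over the list alone, 7 of the 14 passed, all higher, and without dim features 8 of 13 were higher and 0 lower. Some glycolytic genes, picked after their values were seen, read nearly the same on an array. The 12 features of TDH2, TDH3, PGK1, ENO2, FBA1 and CDC19 lay between 0.38 and 0.41 on array 1, the 8 of TDH2, TDH3, CDC19 and FBA1 between 1.13 and 1.17 on array 2, the 6 of TDH2, CDC19 and FBA1 between 0.82 and 0.85 on array 3, and the 4 of CDC19 and FBA1 between 0.50 and 0.51 on array 4. All 14 features of the 7 glycolytic genes of the list, which add ENO1, ran from 0.36 to 0.41, 0.38 to 1.17, -0.81 to 0.85 and -0.33 to 0.51 on arrays 1 to 4. The mean of the features of TPI1, which was outside the list, was 0.60, 0.77, 0.75 and 0.37 on these arrays. Saturation was not checked, since intensities were not used here, so whether CDC19 and FBA1 are separate measurements is open. The housekeeping part of that list held 8 genes with a median of 0.53, and 0.35 as deposited, of which CDC19 and FBA1 were higher over all genes and 5 were higher adjusted over the list alone. With each block of rows centred FBA1 did not pass, while TDH2 and PGK1 were higher beside CDC19. ACT1, ENO1 and ENO2 did not pass, at 0.15 ± 0.0603, 0.18 ± 0.306 and 0.17 ± 0.543 (SD, n = 4), and on the values as deposited all 3 means turned below 0, to -0.038, -0.0082 and -0.015. These lists were the only 2 of the 18 tested that passed camera with its preset correlation, at adjusted p-values of 0.00323 for the abundant and 0.0226 for the housekeeping list. With an estimated correlation both had an adjusted p of 0.560. Fry tests whether the genes of a set move on balance one way, against 0 and not against the other genes. In fry the adjusted p was 0.0726 for the abundant and 0.0840 for the housekeeping list. Without these 7 glycolytic genes, the abundant list had a median of 0.30 and an adjusted p of 0.0684 in camera, and no list passed.

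Of 5 measured genes of beta-1,6-glucan synthesis, 3 were lower and 0 higher. These were KRE6, measured on 3 arrays, at -0.77 ± 0.208, TRS65, at -0.79 ± 0.316, and ROT1. The same 3 passed adjusted over the list alone. The duplicates of TRS65 differed by 0.41 on average. KRE1 and CWH41 did not pass, at 0.17 ± 0.207 and 0.070 ± 0.0422 (SD, n = 4). Camera and fry used only genes with values on all arrays, which left out KRE6. The camera test of this list had an adjusted p of 0.496. In fry its adjusted p was 0.0712, and 0.00321 as deposited, 0.0239 without dim features and 0.0373 with each block of rows centred. As deposited most calls over all genes were lower, and a test against 0 then favours lists that lie lower. With each array left out in turn the adjusted p in fry ran from 0.0706 to 0.167. The 0.0706 was without array 2, the only one of these fits that included KRE6. Of 8 genes of protein mannosylation, MNN9 and PSA1, a GDP-mannose pyrophosphorylase, at -0.45 ± 0.168, were lower and 0 were higher. OCH1, which starts the outer mannan chain, had a mean of 1.37 ± 0.980 and did not pass over all genes. Adjusted over the list alone, 4 of the 8 were lower and 1 was higher. As deposited, where most calls over all genes were lower, 6 of the 8 were lower. The adjusted p was then 0.177 in camera and 0.00321 in fry. Among the 6 genes without a dim feature MNN9, PSA1, KTR6 and KTR2 were lower, with 0.0403 in camera and 0.0130 in fry. The list median was -0.41, with adjusted p-values of 0.0829 in camera, 0.560 in camera with an estimated correlation and 0.00915 in fry. On the centred values of all genes, no other list passed fry. Without dim features the beta-1,3-glucan, general stress, abundant and GPI-anchored lists also passed fry, at adjusted p 0.0158, 0.0158, 0.0316 and 0.0321. With each block of rows centred, the beta-1,3-glucan, chitin and abundant lists also did, at 0.045, 0.0090 and 0.0373. As deposited, cell wall integrity signalling and osmotic, mating and filamentous signalling also passed fry, both at 0.0451. For mannosylation the adjusted p in fry was 0.0517, 0.0460, 0.0567 and 0.0504 without arrays 1, 2, 3 and 4.

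Of 16 measured beta-1,3-glucan genes, 4 were higher and 1 lower. SPR1, GAS4, at 0.45 ± 0.155, SCW10, at 0.38 ± 0.171, and UTR2, at 0.28 ± 0.0644, were higher, and GAS5, a glucanosyltransferase, was lower at -0.99 ± 0.415, both over all genes and adjusted over the list alone. The duplicates of GAS5 differed by 1.87 on average, and without dim features UTR2, SCW10 and SUN4 were higher and 0 of 8 lower. As deposited, SCW10 and UTR2 did not pass, and 2 genes were higher and 1 lower. The catalytic synthase subunits FKS1 and GSC2, paralogs whose cross-hybridisation could not be tested here, did not pass, at 0.49 ± 0.649 and 0.46 ± 0.703 (SD, n = 4). In chitin synthesis, GNA1, at 0.32 ± 0.121, and PCM1, at 0.46 ± 0.126, were higher and QRI1, whose duplicates differed by 0.909 on average, was lower. These were 3 of 8 measured genes, both over all genes and adjusted over the list alone. As deposited QRI1 alone passed, and without dim features GNA1 and PCM1 alone, so the 2 directions stood together in neither setting. The chitin synthase gene CHS3 did not pass, at 0.85 ± 1.72 (SD, n = 4).

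Of 31 GPI-anchored wall proteins, 7 were higher, namely CCW14, CWP2, CCW12, TIR1, TIR3, EGT2 and FIG2, and SAG1 was lower. In total this was near the share called over all genes. The same counts held adjusted over the list alone. The list median was 0.11, and -0.073 on the values as deposited, where EGT2 and FIG2 did not pass and FLO10 was also lower, 5 higher and 2 lower. The list median was 0.27 over the 16 genes without dim features and 0.058 over the 29 genes left without array 4. TIR1 and TIR3, at 0.63 ± 0.233, were also the 2 higher members among 8 seripauperin, TIR and DAN genes, over all genes and adjusted over the list alone, while TIR4 did not pass at 1.77 ± 1.56 (SD, n = 4). EGT2, a gene of daughter cell separation, was higher at 0.35 ± 0.0995, 1 of 3 in its list, again with either adjustment. None of 3 PIR wall proteins, 4 genes of GPI anchor assembly or 3 yapsin proteases passed over all genes, but CIS3 was higher once genes with a dim feature were left out, and GPI1, of GPI anchor assembly, was lower then and as deposited. CIS3 had a mean of 0.46 ± 0.357 and YPS3 of 0.41 ± 0.206, and YPS3 alone passed when adjusted over its list.

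In cell wall integrity signalling, WSC2, a cell surface sensor, at 1.47 ± 0.608, and MKK2 were higher, and the kinase genes PKC1, at -0.44 ± 0.133, BCK1, at -0.50 ± 0.174, and KDX1, at -0.41 ± 0.144, were lower, 5 of 21 measured. That was near the share of 24.9% called over all genes. Adjusted over the list alone, 2 were higher and 5 lower. As deposited, where most calls over all genes were lower, 2 were higher and 6 lower. Among the 13 without a dim feature MKK2 was higher and BCK1, KDX1, WSC4, BEM2 and PTP3 lower. SLT2, the MAP kinase of this pathway, had a mean of 0.0038 ± 0.0816 (SD, n = 4), but its duplicate features on array 1 read -2.05 and 2.08. HOG1 was the 1 gene called among 15 of osmotic, mating and filamentous signalling, with either adjustment. As deposited YPD1, STE11, STE20 and STE50 were also lower, and without dim features YPD1 and STE50 were. Among 16 transcripts known to respond to cell wall stress, KDX1 was lower and 0 were higher, and 0 passed when adjusted over the list alone. Without dim features CIS3 and PRM5 were higher and KDX1 lower, of 9 genes, and with each block of rows centred 0 passed. PIR3, CWP1 and CRH1 of that list had means of 0.11, 0.11 and 0.23, and those of PIR3 and CWP1 were -0.075 and -0.073 as deposited. HSP12, at 0.48 ± 0.183, and DDR2, at 0.64 ± 0.335 (SD, n = 4), were higher among 5 general stress genes, with either adjustment, and 0 of the 5 passed on the values as deposited.

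The third comparison concerned genes that growing cells of this mating type are not known to express. SPR1 and GAS4 were higher among 9 sporulation genes, both over all genes and adjusted over the list alone; as deposited SMK1 was also lower. The list median was 0.47, and it was 0.28 as deposited and 0.28 without array 4, where only 7 of the 9 genes were left. SAG1, the alpha-agglutinin gene of the other mating type, was lower at -0.33 ± 0.106, and MET17, a gene deleted in this strain background, was higher at 0.38 ± 0.0893 (SD, n = 4). Each was the only measured member of its list. All 8 values of the MET17 features were present, 3 of them ratios of whole numbers up to 10, and MET17 did not pass as deposited. Of the genes of the cells' own mating type, AGA2 was higher and MFA1 did not pass, at 0.074 ± 0.184 (SD, n = 4). The 11 measured genes of these silent classes, 3 of them higher and 1 lower over all genes and adjusted over the list alone, had a geometric mean SD 1.18 times that of the 14 abundant genes. Of the 11 silent genes 10 had a dim feature, against 1 of the 14 abundant genes and 39.4% of all tested genes. The comparison of spread is thus largely one of genes with and without a dim feature. The log2 difference of 0.24 did not pass a two-sided permutation test over genes (p = 0.567, adjusted p = 0.894 over 3 tests). It turned to -0.20 without array 3, where 9 of the 11 silent genes were left.

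The fourth comparison was of the error of a single hybridisation. On arrays 1 to 4, 40, 46, 40 and 53 genes lay beyond 2-fold, which was 11.8%, 13.6%, 11.7% and 15.4% of the genes with a value. The SD over genes was 0.80, 0.75, 0.81 and 0.80, and the 95th percentile of the absolute log2 ratio was 1.54, 1.64, 1.71 and 1.70. The spread between arrays was widest for ECM10, a mitochondrial heat shock protein, with an SD of 2.95, followed by GSF2 at 2.76, SSK1, an osmotic response regulator, at 2.51, PLC1, phospholipase C, at 2.17, and DCW1, a putative mannosidase, at 2.13 (n = 4). None of these 5 passed the test of the mean, and each had a dim feature. So did KRE6, GAS4, GAS5, WSC2, TIR3, PKC1, SAG1 and MET17 among the called genes. The median SD was 0.236 over all 345 genes. It was 0.173 over 209 genes without a dim feature and 0.581 over the other 136. Among the 209, 4, 5, 3 and 9 genes lay beyond 2-fold, or 1.91%, 2.39%, 1.44% and 4.31%.

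**Figure D2:**
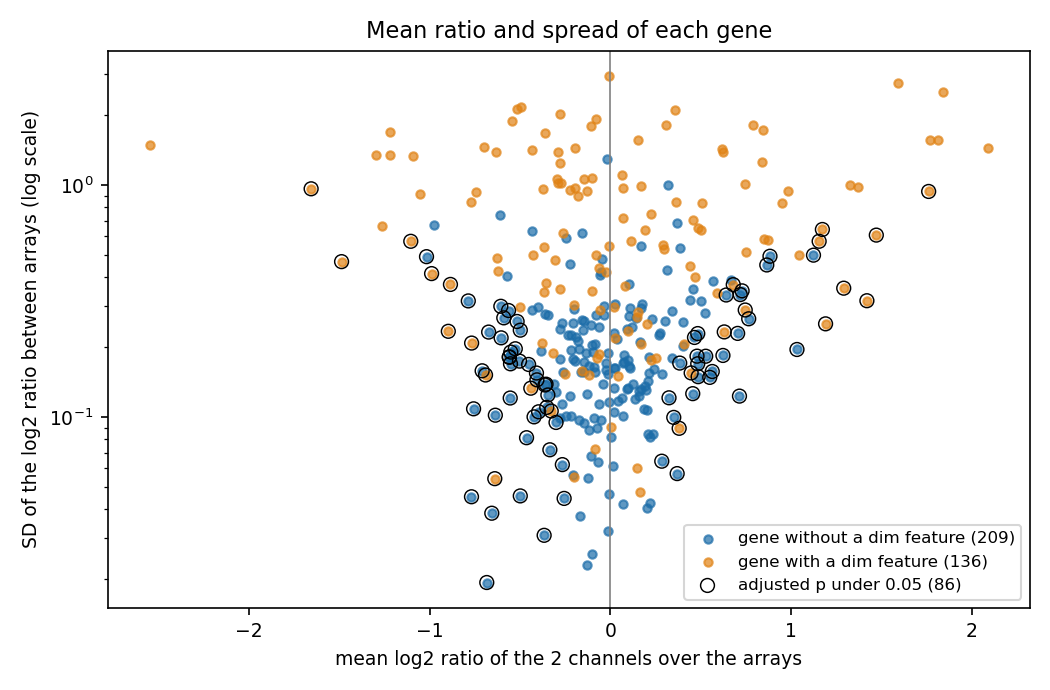
Mean log2 ratio over the arrays (horizontal axis) and SD between the arrays (vertical axis, log scale) of the 345 tested genes. Colours part the 209 genes without a dim feature from the 136 with one, and black rings mark the 86 genes with an adjusted p under 0.05; the widest spreads are mostly of genes with a dim feature.

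The fifth comparison asked whether departures belonged to the gene or to the array. Across genes, which are not independent replicates, the 6 pairs of arrays had Pearson correlations of 0.198 to 0.458 and Spearman correlations of 0.433 to 0.648. The intraclass correlation, the share of variance that lies between genes, was 0.321 (95% bootstrap interval 0.232 to 0.412). Over the 209 genes without a dim feature it was 0.640 (0.548 to 0.718), and the Pearson correlations were 0.592 to 0.721. In these genes 52.6% of the variance lay between genes, 11.8% between arrays within genes and 35.6% between the duplicate features of a gene on an array. Array 1 carried much of the last share: the variance between duplicates was 0.209 there and 0.0694, 0.0345 and 0.0283 on arrays 2 to 4. Without array 1 the shares were 59.4%, 20.3% and 20.4%, and without array 4 they were 49.5%, 5.23% and 45.3%. Each gene kept its rows on every array. The intraclass correlation and the share between genes thus include any effect of position that recurs on the arrays, and cannot tell a gene from its position.

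ACT1, the actin gene, was present 16 times, as a duplicate pair in each of 8 blocks of 112 rows, and so gave the ratio of one transcript along the whole table. Its block means ran from -0.11 to 0.38 with an SD of 0.145, against 0.050 within duplicate pairs. Over the 8 blocks, the means on different arrays correlated at 0.321 to 0.908. The variance of the ACT1 block means was 0.147 of that of the mean ratios of the 209 genes without a dim feature.

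**Figure D3:**
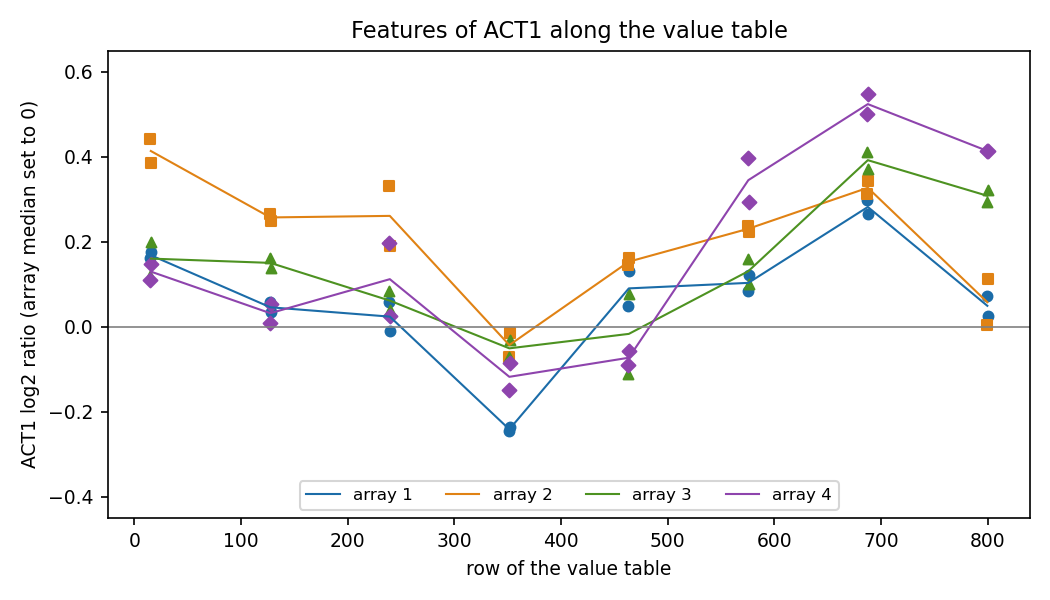
Log2 ratio of each ACT1 feature with the array median set to 0 (vertical axis) by its row in the value table (horizontal axis). Symbols stand for arrays 1 to 4 and lines join the means of the duplicate pairs; the fourth block is the lowest and the seventh the highest on average, at -0.11 and 0.38.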

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

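The rule for a value far from the rest was fixed before the data were examined: the gap of the highest or lowest array to its nearest neighbour, over the whole range of the 4, had to exceed Dixon's 95% critical value. Chance flags about 1 result in 20 by this rule. Of 79 results tested, 7 met it, and of all 327 genes with 4 values 24 did, or 7.34%. MKK2 read 0.36 on array 1 and 0.78 to 0.85 on the others, and ARO10 read -0.95 on array 1 against -0.65 to -0.61. DIT2, a sporulation gene, read -0.51 on array 3 and 2.31 to 2.83 elsewhere. HSP104, a heat shock protein, read 1.57 on array 3 and -1.10 to -0.76 elsewhere. DIT2 and HSP104 each have a dim feature, and MKK2 and ARO10 have none. The median of the genes of GPI anchor assembly was -0.85 on array 2 and 0.05 to 0.14 on the others. The medians of the housekeeping and abundant lists, which share 8 genes, were 1.04 and 0.78 on array 2, against 0.29 to 0.40 and 0.34 to 0.40. On that array the features of TDH2, TDH3, CDC19 and FBA1 all read 1.13 to 1.17, within a range of 0.38 to 1.17 over 7 glycolytic genes. No biological explanation was tested for these values, since every array belonged to the same group.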

How the results depend on the processing

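The settings without dim features, with centring by blocks, with averaging by the median and without glycolytic genes, and the variance shares without 1 array, were chosen after seeing the data; all others were planned. The count of 86 genes stayed within 1.5 times under 11 other settings, from 62 with the robust fit to 112 as deposited, where 70 of the 86 were shared. It was 157 of 691 with each feature by itself, and 0 at an adjusted p of 0.01 and against a 1.2-fold change in limma's treat, where 143 and 74 passed an unadjusted p of 0.05. Leaving out 1 array gave 0 to 1 genes, with 114 to 119 at an unadjusted p of 0.05; the gene was DIT2, at 2.59 without array 3 (limma adjusted p = 0.0461, and 0.113 with all arrays). The simulation with 3 arrays also called fewer genes, 5.25% against 45.5% at a true size of 0.5 and 43.8% against 68.8% at 1. In the data 13 of the 86 lay beyond 2-fold, and whether the number of arrays alone accounts for the loss was not tested. Sign assignments with as many calls then numbered 1 to 4 of 4, which says nothing where 0 genes were called. The mean count of genes beyond 2-fold, 44.8, was 97 at 1.5-fold, 75.8 with each feature by itself and 5.25 without dim features. The median SD of 0.236 became 0.173 without dim features and 0.201 to 0.230 without 1 array. The intraclass correlation of 0.321 became 0.640 and 0.266 to 0.391. The 2 lists past camera became 0 with an estimated correlation and 0 without glycolytic genes, 6 with each feature by itself, 4 without dim features and 2 to 5 without 1 array. With each feature by itself, the 6 lists and the 157 calls count repeats of the same gene as separate members. The log2 difference in spread between silent and abundant genes, 0.24, was 0.67 with each feature by itself (permutation p = 0.0139, too small a value since the 21 and 42 features are repeats of 11 and 14 genes, 16 of them of ACT1), -0.90 without dim features, with 1 gene left in the silent list (permutation p = 0.216), and -0.20 to 0.79 without 1 array. Of the 29 named genes called, 26 passed as deposited (all but EGT2, MET17 and DDR2), 27 with centring by blocks (all but KDX1 and EGT2) and 0 without any 1 array. Of the uncalled ones, YPS3 passed with centring by blocks, at 0.46, and 12 changed sign somewhere. As deposited SLT2 was -0.18, PIR3 -0.075, CWP1 -0.073, ACT1 -0.038, MFA1 -0.11 and ENO2 -0.015; with centring by blocks MFA1 was -0.014 and ECM10 0.0075, and ECM10 was 0.10 with arrays scaled to one MAD. Without 1 array ECM10 ran from -1.36 to 0.99, PLC1 from -1.36 to 0.21, SLT2 from -0.029 to 0.037, PIR3 from -0.025 to 0.19, SKT5 from -0.46 to 0.93, AGA1 from -0.85 to 0.60, YPS1 from -0.16 to 0.0039, FBP26 from -1.10 to 0.32 and ENO2 from -0.045 to 0.37. Except where fewer genes account for it by construction, the cause was not tested. No paired analysis was possible because the arrays form 1 group. The planned turn of signs was not run, since the lowest correlation between arrays was 0.198, above -0.3, nor were other log bases, which the values exclude. Signal over background, which sets the limit for arrays, is unknown here.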

Other observations

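The tests of block centring, of dim features, of a single deviating array and of glycolytic genes were chosen after the result was seen; the tests of neighbouring features, of duplicate differences, of coding length and of paralogs were not. No biological explanation was tested, since both channels of every array held the same RNA.

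Of 124 features with no gene name in the annotation used here and values on at least 3 arrays, 4 were higher and 1 lower, or 4.03%, in a limma fit of their own. Duplicate features of a gene had a median absolute difference of 0.0673, 0.0666, 0.0667 and 0.0708 on arrays 1 to 4 over the 209 genes without a dim feature. Their correlation was nevertheless 0.314 on array 1, against 0.684, 0.792 and 0.895 on the others, and the SLT2 pair of -2.05 and 2.08 lies on array 1.

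The departure of 86 genes from the array median in the limma fit may belong to the labelling or hybridisation of each gene. Against a ratio of 1, on the values as deposited, 70 of the 86 passed. Of the 8 sign assignments of the arrays, 1 gave 86 calls and the highest other gave 0, and 8 assignments cannot give a share under 0.05. Dim features as the whole cause are argued against. Of the 209 genes without one, 44.5% were called in their own fit, against 24.9% of all. In the fit of all genes 30.1% of the 209 and 16.9% of genes with a dim feature were called. After block centring 80 genes passed, 73 of them shared, so differences between block medians do not account for most of the calls. The blocks were inferred from where ACT1 recurs in the row order. Whether block centring removed a position effect such as that of ACT1 was not tested, so a share of it in the calls stays open. Position within blocks, if row order is read as position, stays open: neighbouring pairs had a Spearman correlation of 0.164 (140 pairs, permutation p = 0.0463, adjusted p = 0.0694 over 3 tests). A dye response that depends on brightness and an effect of coding length also stay open, with Spearman correlations of the mean ratio of -0.120 with the duplicate difference, a stand-in for brightness (permutation p = 0.0817, adjusted p = 0.0817), and -0.173 with coding length (permutation p = 0.0113, adjusted p = 0.0339), over 209 genes.

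A candidate explanation of the widest spreads, such as those of ECM10, GSF2 and SSK1, is low signal, which was not measured here. Of the 34 genes with the largest SD, 97.1% had a dim feature, against 39.4% of all tested genes. A single deviating array is argued against, since the array that most often held the largest deviation, array 1, did so in 32.4% of the 34.

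FKS1 and GSC2, which encode alternative subunits of glucan synthase, deviated together between arrays (r = 0.987 over 4 arrays), and transcripts that hybridise to both could give such a pattern. Over 15 other pairs of paralogous genes chosen from background knowledge, the mean correlation was 0.257, against 0.0435 in random pairs (one-sided permutation p = 0.0837). Glycolytic genes that are not paralogs deviated together as well, at a mean of 0.669 over 19 pairs and 1.00 for FBA1 with CDC19 (permutation p = 0.0013, on genes chosen after their values were seen), and without the 2 glycolytic pairs the paralog mean was 0.171 over 13 pairs. A candidate explanation for the glycolytic genes is saturated features. Features at the same ceiling in both channels would read near 0 in unscaled ratios. As deposited, the means of CDC19, FBA1 and TDH2 were 0.545, 0.535 and 0.482. Over all 7 genes the features spread from -0.81 to 0.85 on array 3, while the 6 of TDH2, CDC19 and FBA1 lay between 0.82 and 0.85. The duplicates of FBA1, CDC19 and TDH2 differed by 0.000275, 0.0041 and 0.0042 on average. Those of TDH3, PGK1, ENO1 and ENO2 differed by 0.042, 0.051, 0.13 and 0.33. The median over genes without a dim feature was 0.081. Neither sharing nor saturation could be settled, since probe sequences and intensities were not used here.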
